A study of Homo sapiens with 2 samples.

How the data were processed

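Total RNA from HaCaT cells was measured on Agilent SurePrint G3 human expression arrays, 1 control sample and 1 sample given 1.63 µM cetuximab, both at 24 h, per the labels and the series' design text. RNA was amplified and labelled with Cy3 using a low-input kit, per the labels' protocols, so each array has 1 channel. The deposited values are spot intensities: per the file headers, Feature Extraction 10.7.1.1 with protocol GE1_107_Sep09 quantified each image, subtracted the background and removed spatial and multiplicative trends, and they record no scaling between arrays. Spots at background carry a small positive surrogate value in the processed intensity, per the file headers. Probe positions follow hg19 (GRCh37), per the file headers. Whether cultures were pooled, how long RNA was stored and how dishes were matched is not given in the sources used here. A deposited matrix of the series was not used, because the names of its 2 per-sample columns match no sample label.

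The processed intensity was taken as log2 and each array's 75th percentile over human probes was subtracted. Control spots and spots with an outlier flag (209 on the control array, 228 on the cetuximab array) were left out; no spot was saturated. Spots of a probe were averaged: 902 probes were printed 10 times and 49697 once. A probe counted as measured where the scanner software flagged it well above background on both arrays, and a gene's value is the mean of its measured probes. Of 3957 genes with at least 2 measured probes, all probes went the same way in 68.0%. Symbols were updated through transcript accessions in a RefSeq table used for names only: 20499 of 36337 gene names matched, 2987 of these received another symbol, 8 matched several symbols and kept the array's name, as did all others.

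With 1 array per group no test was run and no p-value is given; the result is the log2 difference, cetuximab minus control, counted at 2-fold. The number of arrays limits the precision, and the spread of replicate spots measures error within an array only. For a gene well above background on 1 array only, the fold is a lower bound: its level on the bright array against the higher of its own level on the other array and the lowest level there among probes well above background (−4.36 on the control array, −4.30 on the cetuximab array). Where its own level there was the higher, the value is the observed ratio between the arrays and not a limit. For 31 gene lists, fixed before the data were examined, the median difference was placed among 10000 random lists of the same size drawn from 10 bins of mean expression. Lists with at least 5 measured genes and a percentile below 2.5 or above 97.5 were said to lie apart. The percentile describes these 2 libraries, since genes are not replicates.

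Genes were named by a rule: the 12 highest and 12 lowest with an official-style symbol, well above background on both arrays, all probes in 1 direction and a mean level above the lower quartile; up to 4 members of each list with the largest absolute difference; EGFR; and the 6 largest bounds per direction among genes seen on 1 array. Any other gene was chosen after its value was seen, except list members seen on 1 array, some of which are given with their bound. LYZ and AKR1C2 are not analysed here, and some genes that the rule selects are not reported here.

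The alternatives were normexp (offset 50) on the deposited mean and local background intensities with limma 3.58.1 in R 4.3.3, quantile, median and loess normalization, the brightest probe per gene, looser and stricter filters on dim probes, folds of 1.5 and 3, detection by the flag for a positive and significant signal, and unmatched random lists. Removal of a trend on probe GC content and scaling to 7 E1A spike-in probes were added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data for cetuximab against control with 17921 genes: 66 of 66 genes made 3-fold different, 66 of 66 made 4-fold different and 0 of 68 made 1.5-fold different came out at least 2-fold apart, as did 0 genes with no difference put in. A list shifted by 0.5 reached percentile 100, and 5 of 100 unshifted lists fell outside the 2.5 to 97.5 percentiles. Both simulated arrays used the control array's levels and detection flags, with the median spread of replicate spots as the only noise. Differences between dishes, RNA preparations or arrays were left out, so the simulation cannot show how many genes differ 2-fold without the drug. The unshifted lists were random genes and do not represent genes that move together.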

Results

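Gene expression was measured in HaCaT cells, an immortalised line of human skin keratinocytes, with and without cetuximab, an antibody that binds the epidermal growth factor receptor (EGFR) and blocks its ligands. The design set 1 sample without the drug (0 µM, the control array) against 1 sample with 1.63 µM cetuximab (the cetuximab array), both at 24 h, and asked which genes accompany the toxicity of the drug in skin cells. There were no replicates, so no test across samples was possible and every difference describes these 2 arrays. Each array carried 50599 human probes, of which 23521 (46.5%) were well above background on the control array and 23608 (46.7%) on the cetuximab array. The median spot signal was 16.9 and 17.1, no spot was saturated, and the median negative control signal was 3.32 and 3.29. Probes printed 10 times gave the error of the measurement within an array: the log2 difference between the arrays from 1 spot had a median SD of 0.084 over 602 such probes, rising from 0.061 in the brightest group of these probes to 0.155 in the dimmest. That spread leaves out differences between dishes. Differences are given as log2 values, cetuximab minus control, and probe positions are those of the files on hg19 (GRCh37), without exon or UTR annotation.

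Keratin 1, 14 of 17 chemokine genes, all 25 interferon-stimulated genes measured and 4 S100 genes (at least 2-fold) were higher on the cetuximab array. IL1R2, ANXA10, probes for vault RNAs and several hypoxia genes were lower. KRT1, the type II keratin that keratinocytes switch on when they leave the basal layer, was furthest apart, at 73.6-fold higher (log2 6.20, or 4.53 with normexp background correction). The genes IL6, CCL20, IFI44L and S100A7 were each more than 4-fold higher. Mitosis genes lay lower as a group, with 20 of 25 below 0 and none 2-fold apart. Of 17128 genes measured on both arrays, 549 were at least 2-fold higher and 350 at least 2-fold lower on the cetuximab array, together 5.2% of the genes, and 54 and 11 passed 4-fold. The median difference over all genes was −0.02 and the middle 95% ran from −0.94 to 1.11. The share of 2-fold genes that were higher, 61.1%, depends on the scaling: with the E1A spike-in RNAs set equal between the arrays, the median of all genes moved to −0.19, and 386 genes were at least 2-fold higher against 608 lower (38.8% higher). With normexp background correction, which shrinks differences of dim probes, 222 and 113 genes passed 2-fold, all of them among the 549 and 350.

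**Figure D1:**
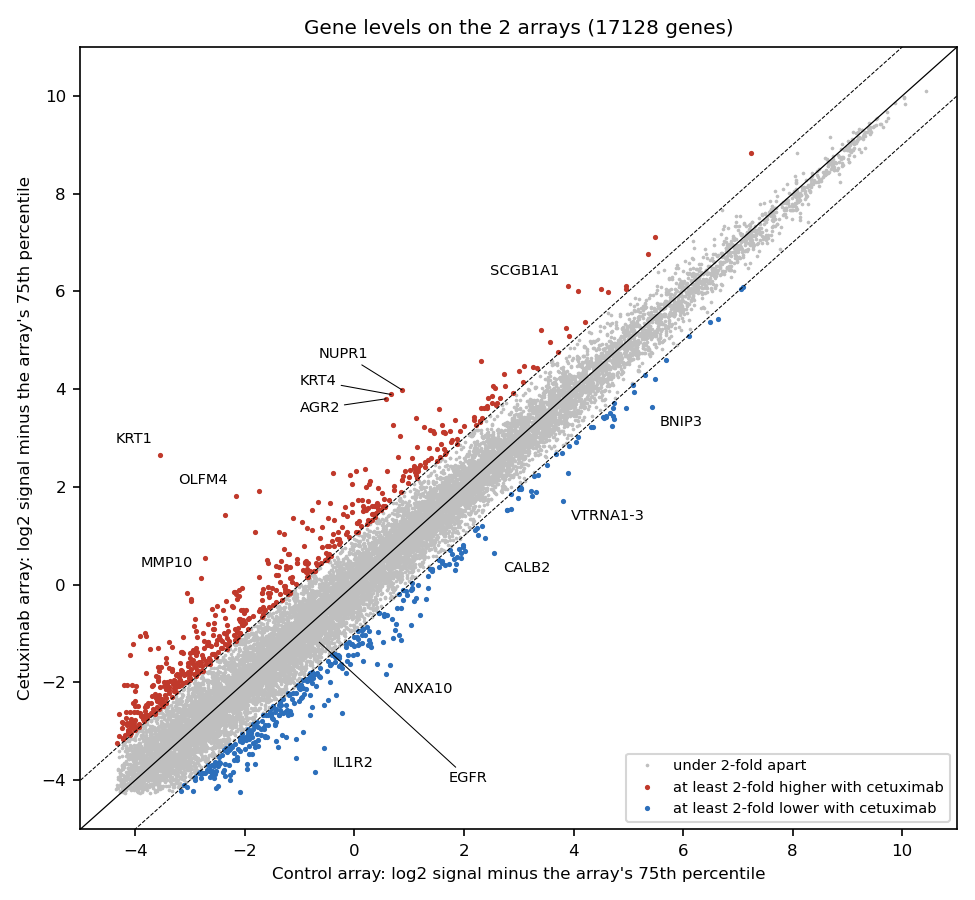
Level of each of the 17128 genes measured on both arrays, as log2 signal minus the array's 75th percentile, on the control array (x axis) and the cetuximab array (y axis). The solid line marks equal levels and the dashed lines a 2-fold difference; 549 genes lie at or above the upper line (red) and 350 at or below the lower line (blue), with KRT1 furthest from the solid line, and EGFR lies between the dashed lines.

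KRT1 had a log2 level of −3.54 on the control array and 2.66 on the cetuximab array, a difference of 6.20, from 1 probe on chromosome 12 (53068520 to 53068579). OLFM4, a secreted glycoprotein of epithelia, was 15.7-fold higher (3.97; chromosome 13, 53626095 to 53626154). GPR15LG, named C10orf99 on the array and encoding a secreted peptide of barrier epithelia, was 12.7-fold higher (3.67; chromosome 10, 85944973 to 85945032). AGR2, a disulfide isomerase of secretory epithelia (chromosome 7, 16837274 to 16839382), and KRT4, a keratin of mucosal epithelia (chromosome 12, 53200511 to 53200570), were 9.35-fold and 9.32-fold higher. The stress-responsive regulator NUPR1 was 8.67-fold higher and the matrix metalloproteinase gene MMP10 7.66-fold higher. PHGR1 (3.29), PIGR (2.90), which encodes the receptor that carries polymeric immunoglobulins across epithelia, MYL7 (2.88), HPGD (2.70), which encodes the enzyme that inactivates prostaglandins, and TMT1A (2.67; METTL7A on the array) completed the 12 highest.

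The decoy receptor gene for interleukin 1, IL1R2, was lowest on the cetuximab array relative to control, at 6.88-fold lower (−2.78), from a probe on chromosome 2 whose ends map to 102632505 and 102636150. ANXA10, a member of the annexin family, was 5.27-fold lower (−2.40; chromosome 4, 169108564 to 169108623). The small noncoding vault RNAs VTRNA1-3 (−2.10; chromosome 5, 140105752 to 140105811) and VTRNA1-2 (−1.99; chromosome 5, 140098539 to 140098598) were both among the 12 lowest. TNFRSF6B, which encodes a decoy receptor for FAS ligand, was lower by 4.10-fold and the transcription factor gene TOX2 by 4.23-fold. The others were CALB2 (−1.90), NGEF (−1.87, SE over 10 spots 0.086), the neuropeptide gene GAL (−1.86), GNG4 (−1.85), ARRDC4 (−1.83) and CD68 (−1.80). With no background filter, which adds dim probes to a gene's mean, GAL was at −0.80 and GNG4 at −0.83. The sizes depended on the background correction: with normexp the difference was 4.53 for KRT1, 3.15 for OLFM4 and −1.59 for IL1R2.

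**Figure D2:**
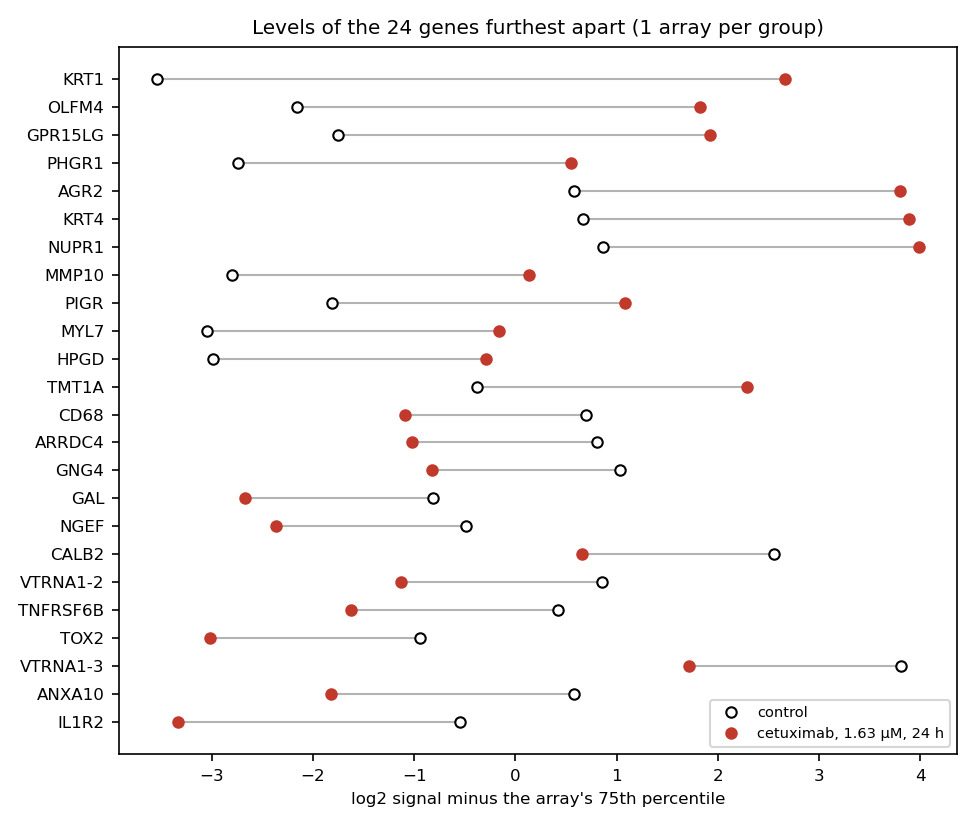
Log2 level (signal minus the array's 75th percentile, x axis) of the 12 highest and 12 lowest genes on the control array (open circles) and the cetuximab array (filled circles), with a grey line joining the 1 value per array. KRT1 runs from −3.54 to 2.66 and IL1R2 from −0.55 to −3.33.

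EGFR itself, the target of the antibody, was 1.45-fold lower on the cetuximab array (−0.54), below the 2-fold mark. Its 3 measured probes on chromosome 7 gave −0.70 (55224558 to 55224617), −0.31 (55231446 to 55231505) and −0.59 (55274841 to 55274900). Among 12 measured receptors, ligands and regulators of the EGFR family, only the ligand gene BTC was at least 2-fold apart (1.29), near background. The ligand genes EREG (−0.84), AREG (−0.74), EPGN (−0.62) and TGFA (−0.23) were lower, and the ligand gene HBEGF (0.59) was higher. The list's median of −0.19 lay at percentile 10.7 of 10000 random lists of equal size matched on mean expression, which describe these 2 libraries only. Of 19 measured ERK pathway targets, ETV4 (−2.10) and FOSL1 (−1.48), both transcription factor genes that ERK signalling induces, were at least 2-fold lower, and EPHA4 (2.41, SE over 10 spots 0.094) and FOS (1.04) higher. The ERK-induced genes ETV5 and SPRED2 were well above background on the control array only, at least 1.68-fold and 1.62-fold higher there. DUSP6 (−0.24) and CCND1 (0.31), chosen after their values were seen, were under 2-fold. The list's median of −0.09 lay at percentile 24.6, but it was below the range of the random lists with the brightest probe per gene (−0.24, percentile 2.46), with genes above background on at least 1 array (−0.39, percentile 0.03) and with no background filter (−0.24, percentile 1.72).

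Keratinocyte differentiation genes were divided. Of 15 measured genes, KRT1, the cornified envelope precursor IVL (1.57), the lipid transporter gene ABCA12 (1.43) and CALML5 (1.29) were at least 2-fold higher and none was 2-fold lower. The list's median of 0.15 lay at percentile 90.4 and turned to −0.02 with spike-in scaling. KRT10, the partner of KRT1 in suprabasal filaments and chosen after its value was seen, was at 0.15 (−0.02 with spike-in scaling), and 12 of the 29 genes listed, LOR and FLG2 among them, were not well above background. In the basal and hemidesmosome list (17 genes, median 0.00, percentile 64.0), KRT15 (1.60) and the integrin gene ITGA2 (1.53) were higher, and the hemidesmosome linker PLEC (−1.32) lower. The S100 genes S100A7 (2.27, SE over 10 spots 0.023), S100A8 (1.62), S100A12 (1.54) and S100A9 (1.20), which encode proteins abundant in inflamed epidermis, were the members at least 2-fold higher among 11 stress keratins and S100 genes, whose median of 0.18 lay at percentile 97.3. That median was 0.01 with spike-in scaling and 0.39 both with genes above background on at least 1 array (percentile 99.92) and with no background filter (percentile 99.84). Of 6 measured antimicrobial genes, the defensin DEFB1 (1.81) and the elastase inhibitor PI3 (1.08) were at least 2-fold higher, with a median of 0.57 at percentile 99.9 (0.25 with no background filter); PI3 was at 0.91 with spike-in scaling. The serpins SERPINB3 (1.37) and SERPINB4 (1.30) were the 2-fold members among 14 epidermal kallikreins and serpins (median 0.26, percentile 99.5; 0.09 with spike-in scaling), and KLK13 was at −0.99. SPINK6, a kallikrein inhibitor of the same list, was well above background on the control array only, at least 2.11-fold higher there. Of 17 junction genes, 5 were at least 2-fold higher, among them the tight junction gene CLDN1 (1.53), the desmosomal cadherins DSG3 (1.29) and DSC3 (1.10) and the connexin GJA1 (1.14), with a median of 0.33 at percentile 99.9 (0.17 with spike-in scaling).

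Interferon-stimulated, chemokine and antigen presentation genes were higher as groups. All 25 interferon-stimulated genes measured lay above 0, and 11 were at least 2-fold higher, led by IFI44L (2.17), OAS1 (2.82-fold), OAS2 (1.47) and IFIT1 (1.40). Their median of 0.91 lay above every one of the 10000 random lists (percentile 100). The 3 probes of OAS2, a sensor of double-stranded RNA, disagreed in size, from 0.39 to 2.26. Of 17 chemokine genes, 7 were at least 2-fold higher and none 2-fold lower (median 0.87, percentile 100). They included CCL20 (2.30), a chemoattractant for CCR6-bearing lymphocytes, the interferon-induced CXCL10 (1.86, 0.83 with normexp), and the neutrophil attractants CXCL2 (1.59) and CXCL3 (1.57). Antigen presentation genes had a median of 0.45 at percentile 100, and the 3 of 14 that were at least 2-fold higher all belong to the MHC class II pathway: HLA-DPA1 (2.01), HLA-DRA (1.80) and the invariant chain CD74 (1.40, 0.60 with normexp). CIITA, the coactivator of class II genes, was well above background on the cetuximab array only, with an observed ratio of 3.95-fold to its dim control signal. Cytokines and their receptors went both ways (16 genes, median 0.05, −0.12 with spike-in scaling, percentile 75.04), with IL6 (2.21), IL13RA2 (1.22) and IL36G (1.03) at least 2-fold higher, and IL1R2, the signalling receptor gene IL1R1 (−1.29) and CSF2 (−1.18) at least 2-fold lower. IL1B was at −0.81 and TNF at −0.54; these and IL36G and CSF2 were chosen after their values were seen. Of 9 listed leukocyte markers, HLA-DRA, CD14 (0.80) and CD68 (−1.80) were measured on both arrays, the pan-leukocyte gene PTPRC was well above background on the control array only, at least 1.82-fold higher there, and 4 were not well above background on either array.

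Mitosis genes were lower and replication genes showed no common direction. Of 25 mitosis genes, 20 were below 0 and none reached 2-fold, with CDK1 (−0.90), CCNA2 (−0.85, SE over 10 spots 0.020), CENPA (−0.72) and PLK1 (−0.54) the furthest apart. Their median of −0.31 lay at percentile 0.02 (−0.48 with spike-in scaling). Of 24 DNA replication genes none was 2-fold apart, the helicase subunit genes MCM2 (0.68) and MCM3 (0.62) were higher, and the median of −0.05 lay at percentile 43.2 (−0.21 with spike-in scaling). Among 15 CDK inhibitor and growth arrest genes, the CDK inhibitors CDKN2B (1.97), CDKN1A (1.87) and CDKN1C (1.37) and the stress gene GADD45G (1.01) were at least 2-fold higher and TXNIP (−1.26) lower, while CDKN1B was at 0.18 and CDKN2D at −0.69. The list's median of 0.19 lay at percentile 95.9 (0.03 with spike-in scaling). Among 22 p53 target and apoptosis genes, GDF15 (2.23), a stress-induced cytokine, TP53INP1 (2.06), TP53I3 (3.13-fold higher), BMF (1.14) and CASP8 (1.18) were at least 2-fold higher and none 2-fold lower. Their median of 0.10 lay at percentile 89.5, or at −0.07 with spike-in scaling. GADD45G, CDKN1B, CDKN2D and BMF were chosen after their values were seen.

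Endoplasmic reticulum stress and ATF4 target genes had a median of 0.27 (18 genes, percentile 99.9; 0.11 with spike-in scaling), with DDIT3 (1.22), a transcription factor of the unfolded protein response, the chaperone HSPA5 (1.22) and ATF3 (1.21, probes from 0.31 to 1.55) at least 2-fold higher and DDIT4 at −0.73. All 19 cholesterol biosynthesis genes lay above 0 (median 0.50, percentile 100, 0.33 with spike-in scaling), among them MVD (1.39), HMGCS1 (0.98) and DHCR7 (0.96). SQLE (0.04), INSIG1 (0.08), SREBF2 (0.15) and IDI1 (0.15) lay within the spike-in shift of 0.17, so with that scaling they fall below 0. Of 15 fatty acid and epidermal lipid genes only PPARD (−1.38) was 2-fold apart, SCD was at 0.86, and the median was −0.05 (percentile 36.2). Glycolysis and hypoxia genes were lower (21 genes, median −0.28, percentile 0.47; −0.45 with spike-in scaling): the mitophagy receptor BNIP3 (−1.78), PDK1 (−1.59), which encodes a kinase that inhibits pyruvate dehydrogenase, and ENO2 (−1.45, −0.49 with normexp) were at least 2-fold lower, while ADM was higher (1.41, SE over 10 spots 0.018). CA9, another hypoxia gene, was well above background on the control array only, at least 2.47-fold higher there. The NRF2 list had a median of −0.04 (18 genes, percentile 57.6) with HMOX1, the heme-degrading enzyme, the sole 2-fold member (1.76, SE over 9 spots 0.028). Heat shock genes had a median of 0.12 (12 genes, percentile 93.3; −0.05 with spike-in scaling), with HSPA1A (1.24) and HSPB8 (1.06) at least 2-fold higher, and the 3 probes of HSPA8 ran from −1.54 to 0.43.

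Among 15 matrix metalloproteinase and plasminogen genes, 5 were at least 2-fold higher, including MMP10 and the collagenases MMP1 (1.96, SE over 10 spots 0.023) and MMP13 (3.08-fold higher). The median of 0.15 lay at percentile 90.2 and turned to −0.02 with spike-in scaling. MMP12 was well above background on the cetuximab array only, at least 6.56-fold higher. Of 14 mesenchymal and matrix genes, TGFB1 (−1.46, SE over 10 spots 0.060) and VIM (−1.21) were at least 2-fold lower and SPARC (1.23) higher. Their median of −0.02 lay at percentile 48.2, and turned to 0.21 with genes above background on at least 1 array and to 0.29 (percentile 99.1) with no background filter. Ribosomal protein genes, with 20 measured and none 2-fold apart, had a median of −0.09 (percentile 51.1). The housekeeping list had a median of −0.04 (15 genes, percentile 66.7), ACTB was at −0.51, and the transferrin receptor gene TFRC stood out at 1.81 (SE over 10 spots 0.022). Markers of other cells were mostly not well above background on both arrays. Those measured were DPT (0.15) of 11 fibroblast genes, PMEL (0.42) and MITF (0.34) of 7 melanocyte genes, CDH5 (−0.10) of 6 endothelial genes, and NEFL (0.94), CDH2 (−0.25) and HOXD10 (−0.16) of 10 genes of the human embryonic kidney line that the RNA protocol also names.

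**Figure D3:**
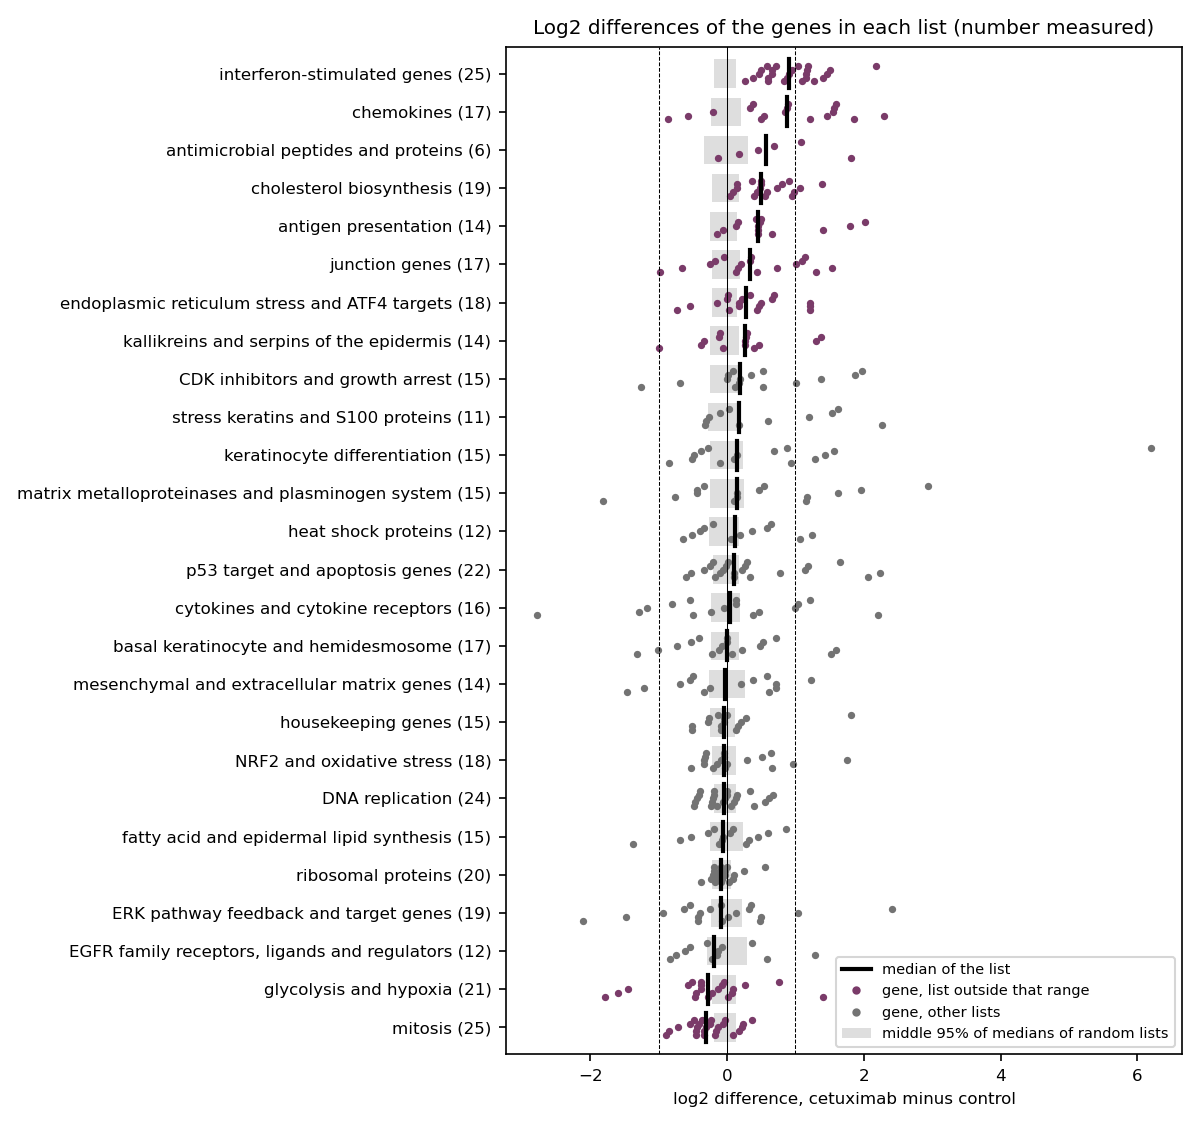
Log2 difference (cetuximab minus control, x axis) of each measured gene in the 26 lists with at least 5 measured genes, with the list's median (black bar) and the middle 95% of the medians of 10000 random lists matched on mean expression (grey box). Purple points mark the 8 lists with a median above that range and the 2, mitosis and glycolysis and hypoxia, below it; dashed lines mark 2-fold.

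A further 881 genes were well above background on the cetuximab array only and 776 on the control array only. Their fold is a lower bound, or the observed ratio where the dim level exceeded the lowest level well above background there. It exceeded 2-fold for 166 and 123. The largest folds on the cetuximab side were 14.5-fold for the transcript XLOC_013929 and 7.92-fold for FHDC1, both observed ratios. Next were bounds of at least 7.91-fold for XLOC_l2_007788, 7.26-fold for ATP13A5, 7.07-fold for MTMR8 and 6.96-fold for XLOC_003739. On the control side the largest bounds were at least 6.21-fold for MYOZ1, 6.05-fold for TDRD10, 5.60-fold for XLOC_008395, 5.57-fold for ENST00000391612, 5.36-fold for the probe A_33_P3397593 and 5.12-fold for UBTFL1. S100A7A, at least 2.38-fold higher, and the differentiation gene KRTDAP, with an observed ratio of 1.65-fold, were well above background on the cetuximab array only.

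Both arrays lay on 1 slide and each group on 1 array, so the drug, the dish and the array cannot be told apart. Close paralogs such as SERPINB3 and SERPINB4, CXCL2 and CXCL3 or the class II genes can share probe signal and were not separated. With normexp, BTC, FOS, ABCA12, ITGA2, PLEC, IL1R1, IL13RA2, CDKN1C, CASP8, HSPB8, PPARD, TGFB1, SPARC, VIM, GJA1 and DSC3 were also under 2-fold. Of 116 genes with several measured probes and a difference of at least 2-fold, 115 had all probes on the same side of 0. Selection on the mean of the same probes favours such agreement, which held for 68.0% of all 3957 genes with several measured probes.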

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

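The GC correction and the spike-in scaling were chosen after seeing the data; all other alternatives here were planned. No named gene at least 2-fold apart changed sign under any alternative run on gene values, while HSPA8, under 2-fold, went to 0.43 with its brightest probe. Genes at least 2-fold apart were picked by their size in these data, which made a change of sign unlikely. The counts of 2-fold genes, 549 higher and 350 lower, depended on the treatment of dim probes: 222 and 113 with normexp, 1049 and 735 with probes above background on at least 1 array, 2321 and 1441 with no background filter, and 196 and 102 among genes above the median level. They were 1655 and 1453 at 1.5-fold and 134 and 41 at 3-fold. Spike-in scaling gave 608 lower. Quantile, median and loess normalization, the brightest probe and GC correction left 531 to 580 higher and 321 to 380 lower, and no spot was saturated. EGFR stayed below 0, at −0.39 with normexp and, with the brightest probe and with spike-in scaling, −0.70 each. Bounds over 2-fold numbered 1154 (cetuximab) and 704 (control) when detection used the flag for a positive and significant signal. Of the 10 lists that lay apart, 9 did so in 10 of 10 alternatives, and junction genes missed in 1, at percentile 97.1 with no background filter. Median centring and spike-in scaling, counted among these alternatives, subtract the same constant from every gene. They could therefore not change the percentile of any list. Other lists lay apart in an alternative only: ERK targets, lower, with the brightest probe (percentile 2.46), with probes above background on at least 1 array (0.03) and with no filter (1.72); stress keratins and S100 genes, higher, in the last 2 of these (99.92 and 99.84) and after GC correction (98.35); heat shock (99.92) and growth arrest genes (98.2), higher, with the brightest probe; metalloproteinases (99.27), higher, with probes above background on at least 1 array; and mesenchymal genes (99.13), higher, with no filter. Spike-in scaling lowered every median, to 0.74 for interferon-stimulated, 0.71 for chemokine, 0.40 for antimicrobial, 0.33 for cholesterol and 0.29 for antigen presentation genes. Of 105 named genes at least 2-fold apart, 30 fell under 2-fold in some alternative, mostly with normexp: BTC was then at 0.46, ITGA2 at 0.51, CD74 at 0.60, CXCL10 at 0.83, ENO2 at −0.49 and VIM at −0.37, and OAS2 was at 0.39 with its brightest probe. Beyond the filters' own construction, the cause was not tested. The authors' deposited matrix was planned as an alternative and not run, because its columns could not be assigned to arrays. Signal over background limits the dim genes: 46.5% and 46.7% of probes were well above it on the 2 arrays. No paired analysis was possible because each group has 1 array.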

Other observations

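The gene classes and single genes in this part, and the test of leukocyte genes, were chosen after the values were seen. MHC class II genes were higher well beyond the members already named: of 15 measured, 14 were at least 2-fold higher on the cetuximab array, with a median of 1.82 (1.65 with spike-in scaling, 1.58 with normexp), and 3 of them also stand in the antigen presentation list. HLA-DQA1 (2.67), the peptide loading genes HLA-DMB (5.01-fold higher) and HLA-DMA (2.10), and HLA-DPB1 (1.90) were among them, and HLA-DOB (0.44) was the exception. Several of these probes belong to close paralogs. Other interferon-responsive genes were as far apart, with BST2 at 2.29, XAF1 at 2.27 and GBP2 at 2.11. The mucosal keratin KRT13 (1.93), the partner of KRT4, and the airway secretory protein gene SCGB1A1 (2.21) were higher, as were the contractile genes TAGLN (2.57) and MYL9 (1.77) and the claudin CLDN8 (1.81, 0.79 with normexp). The simple epithelial keratins KRT18 (2.02-fold lower, −0.91 with quantile normalization) and KRT8 (−0.72) were lower and KRT19 (0.76) higher.

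Probes for small noncoding RNAs were lower in part. Whether their signal came from the small RNAs themselves was not tested. All 4 vault RNAs measured were at least 2-fold lower, among them VTRNA1-1 (2.72-fold lower) and VTRNA2-1 (−1.16), which with normexp stood at −0.82 and −0.87, with a class median of −1.72 (−1.21 with normexp). Of 217 small nucleolar RNAs, 190 lay below 0, with a median of −0.34 for 119 C/D box genes and −0.27 for 98 H/ACA box genes. The 22 small Cajal body RNAs did not share this (median −0.02, percentile 46.1), and 58 core histone genes had a median of −0.15 (percentile 4.0). Of 96 ERCC control probes, 3 and 2 were well above background on the control and cetuximab arrays.

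The higher level of interferon, chemokine and antigen presentation genes covered 56 genes with a median of 0.78. A trend on probe GC content is argued against, since the difference hardly followed it (Spearman's rho −0.05 across 22393 probes). Removing so weak a trend could change the median little, and it was 0.79 afterwards. The bootstrap interval of 0.58 to 1.03 describes the spread over these genes, which are not independent replicates. Leukocyte RNA in the cetuximab sample stays open: of 4 listed leukocyte genes well above background on either array, 2 were higher on the cetuximab array (CD14 and HLA-DRA, the latter also in the antigen presentation list) and CD68 and PTPRC were lower, and IKZF1, a lymphoid transcription factor gene outside the list, was at least 5.99-fold higher on the cetuximab array only. The drug itself, and a difference between dishes in handling or density, also stay open and were not tested.

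KRT1 stood far above other differentiation genes, from a processed signal of 26.2 on the control array to 1842 on the cetuximab array, on a single spot. Light from a bright neighbouring spot is argued against: 0 of 4 neighbours were both brighter and at least 2-fold higher on the cetuximab array, and the 1 brighter neighbour, SDC4, went from 4366 to 5345. No second probe tested the value, and a denser dish, which is known to induce KRT1 in keratinocytes, could produce the same difference and was not tested.

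The lower small nucleolar RNAs, with a median of −0.31, are not accounted for by the trend on probe GC content. That trend was weak, and the median was −0.28 (bootstrap interval over genes −0.32 to −0.22) after it was removed. Weaker recovery of the shortest RNAs in the cetuximab sample stays open: Spearman's rho of the difference with RNA length was 0.15 (interval 0.01 to 0.27) across 217 genes, which are not independent replicates, and the value fell between the ranges set beforehand for and against it. A lower level of these RNAs with the drug also stays open and was not tested, and 1 array per group cannot separate the alternatives.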
